A study of Rattus norvegicus with 120 samples.

How the data were processed

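The deposited values were gene expression levels of 120 rat eye RNA samples, 1 Affymetrix array for each animal. Per the labels' protocols, both eyes of a 12-week-old male F2 rat were pooled, RNA was extracted with TRIzol and purified on RNeasy columns, and labelled by the one-cycle method. The authors deposited log2 values made by robust multi-array averaging (RMA), per the submitters' processing notes, in which no version is given. The array annotation and genome build behind the values were not given in the sources used here. The table held 31099 probe sets, of which 57 were controls and 31042 were others. RMA removes background, brings the distributions of the arrays closer and summarises the probes of a set, so a change shared by most genes may be hidden in its values. A probe that binds the transcript of one strain poorly can look like a difference in level. The distributions of the deposited values were not fully alike, with 75th percentiles between 7.11 and 7.71 over the arrays.

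Probe sets were named through the platform's annotation, updated by Entrez number with a RefSeq gene table of the GRCr8 assembly, which was used only for names and for which genes neighbour each other. Of the probe sets that were not controls, 20832 had 1 symbol, 436 had several and 9774 had none, and none was named from a probe set with several. The Entrez number of 20764 of those with 1 symbol was in the RefSeq table. Probe sets with a mean at or above the 25th percentile of all values (4.283 on the log2 scale) were tested, 23326 in all, and 12326 genes were represented by the probe set of highest mean. The 32 gene lists held 464 members, of which 384 were used, 15 were below the filter, 65 had no probe set of their own and 5 had been renamed.

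The labels put all animals in 1 group. The titles hold a pair of codes, S (10 codes of 11 to 13 arrays) and L (22 codes of 2 to 11 arrays), neither explained in the labels, and the S code is called the processing set here because it goes with the dates in the titles, although the labels do not say what these dates are. The titles mark 3 arrays as scanned again. Except where stated otherwise, the mean of each S code was removed from each probe set before analysis. No pair of arrays was alike enough to be 1 sample deposited again (smallest SD of the difference 0.173). The number of arrays limits the precision. The p-values of the code tests and of correlations between single genes or scores measure the spread between animals together with that of single arrays. Those from random lists, shuffled gene positions or permuted chromosomes hold the animals fixed and measure the spread over genes. The p-value of the clock gene groups measures the spread over L codes.

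Variation was read as the SD and the range over animals, with a range of at least 2-fold as the threshold for counts, and median SDs of lists were set against 10000 random lists matched on size and mean level. S and L codes were tested with limma's moderated F test, the L code with the S code as covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. An F2 mixture was called where the BIC of 3 normal distributions with weights of 1:2:1 and a common SD was lower by more than 10 than that of the best of 3 single distributions (normal, t and skew-normal). Correlations of neighbouring genes were compared with 1000 shuffles of gene positions, those within lists with 10000 random lists, and those between lists, as Pearson r of list scores, with 100000 permutations within processing sets.

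The named genes were 1 probe set per gene, of highest mean or, for the mixture, of largest BIC difference. They were the 25 genes of largest SD, the 12 of largest moderated F for each code, the 25 of largest BIC difference among those called, the 10 most correlated neighbouring pairs, up to 3 gene pairs of each list past its threshold, the 6 most positive and 6 most negative list pairs, and the sex check genes. This rule, the lists, the tests and most of the alternatives were set before the data were examined. The alternatives were no removal of set means, no filter, the rescanned arrays left out, array medians subtracted, L code effects also removed, 5 principal components removed, Spearman rho, other thresholds, other covariates, each S code left out, and another probe set per gene. Leaving out the 2 arrays least like the rest (animals 63 and 15), leaving out animal 63 or 77 alone for the list results, regressing out the actin and GAPDH 3' to 5' differences, leaving out overlapping genes, the interferon score as a covariate, and, for the variation counts, the removal of 5 principal components were chosen after seeing the data.

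The code tests, the mixture call, the correlation within lists and the neighbour test were tried on simulated or shuffled data, and the other tests were not. Of 200 probe sets among 23326 given a code effect with an SD equal to the residual SD, 95.5% were called for S and 94.5% for L, and 47% and 8% at a ratio of 0.5, with at most 6 false calls. Of mixtures with neighbouring levels 2, 3, 4 and 5 within-level SDs apart, 0%, 0.5%, 26.5% and 54.5% were called. The mixture test thus misses nearly all loci with levels up to 3 SDs apart and many with levels further apart. Its count is therefore not a full count of genes controlled by 1 locus. It called 0.025% of normal values, none of the t or gamma values, and 72% of 1:1 mixtures 4 SDs apart, so a call is not specific to 1:2:1. With shuffled values no list was called, and 3 of 3 lists given a common factor were. Each gene was shuffled on its own, which removes correlation shared by many genes, so calls in the presence of such correlation were not tried. Over shuffled positions the neighbour test gave p = 0.189, and p = 0.005 with a common factor in 200 pairs.

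Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. Genotypes and probe sequences were not used here, so no locus was mapped.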

Results

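The series profiled messenger RNA in the eyes of 120 adult male rats. All were 12 weeks old and belonged to the F2 generation of a cross between the inbred strains SR/JrHsd and SHRSP, the second of which is a stroke-prone line of spontaneously hypertensive rats. In an F2 generation each animal draws its own mixture of the parental genomes, and the study was designed to find loci that set expression levels in the eye (expression quantitative trait loci). RNA from both eyes of an animal was pooled and hybridised to 1 Affymetrix array, without replicate arrays, so the spread between arrays holds the difference between animals together with the error of a single measurement. Genotypes were not used here, and the labels place all 120 animals in 1 group. The results below therefore describe how genes varied between animals, which genes followed the codes in the sample titles, which had the shape that a single segregating locus gives, and which varied together. Array medians lay between 5.78 and 5.96 on the log2 scale and 75th percentiles between 7.11 and 7.71, so differences across whole arrays remained. The number of arrays limits the precision of every value.

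Sex-linked transcripts matched the labels, which call all animals male. The Y-linked gene Eif2s3y had a log2 level between 7.64 and 9.19 in the 120 animals, and 1 of the 2 Uty probe sets lay between 6.47 and 8.66, while the other stayed between 3.16 and 4.52. Xist, the transcript that coats the inactive X chromosome of females, stayed at or below 4.42 on each of its 4 probe sets, near the level of the second Uty probe set. Kdm5d and Ddx3y were not analysed here. The array of animal 63, which had been scanned again, had the lowest median correlation with the other arrays (0.937), followed by that of animal 15 (0.970), against a median of 0.989 over all arrays.

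Variation between animals was largest for a small set of genes of diverse function. With each gene read from its probe set of highest mean, the cadherin gene Cdh22 varied most, with a log2 level of 7.03 ± 1.57 (SD, n = 120) once the mean of each processing set had been removed. It was followed by the major histocompatibility complex (MHC) class II gene RT1-Bb (SD 1.44), the synaptic vesicle gene Sv2b (1.44), Frmd4b (1.42), the matricellular gene Ccn1 (1.29) and the protease inhibitor gene Stfa3 (1.28). The lowest and highest animal differed 68.8-fold for Sv2b. The 25 genes of largest SD also held the interferon-induced GTPases Mx1 and Mx2 (SD 0.81 each), Chac1 and Mthfd2, which respond to amino acid stress (0.75 and 0.73), the transcription factors Nfib, Rora and Ikzf2 (0.80, 0.74 and 0.72), the cyclin gene Ccnd2 (0.78) and the inositol transporter gene Slc5a3 (0.81). Ythdf2, Krtap14l, Pde10a, Ly6c, Stk25, Fabp12, Rasal2, Rnf6, Rab8b and Cbr1 made up the rest, with SDs between 0.71 and 0.95. For Cdh22, Sv2b, Frmd4b, Ythdf2 and Rab8b another probe set of the same gene had an SD between 0.16 and 0.31. With the first 5 principal components of all arrays removed as well, the SD fell by more than 1.5 times for 7 of the 25, namely Rora (to 0.20), Ikzf2 (0.28), Ccnd2 (0.29), Rasal2 (0.30), Nfib (0.34), Slc5a3 (0.41) and Mthfd2 (0.48), where the first of those components had an absolute r of 0.784 with the actin 3' to 5' difference.

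Of the 32 gene lists, 14 had a median SD above the middle 95% of random lists of the same size and mean level, and 2 lay below it. The 13 interferon-response genes had the largest median SD (0.415 against 0.153 in random lists). Those of the lacrimal and Harderian glands, the glands beside the eye, followed at 0.36 over 5 genes, with Scd at 0.56 and Lpo at 0.41. The glucocorticoid-response list (median 0.298, led by Pdk4 at 0.69 and Fkbp5 at 0.45), the immediate early genes (0.279), skeletal muscle (0.208 over 24 genes) and the circadian clock (0.208 over 17 genes, led by Bhlhe40 at 0.31) each exceeded all 10000 random lists or, for the gland list, 99.99% of them. Cone photoreceptor genes (0.220), MHC class I genes (0.216), red blood cell genes (0.259), outer segment genes (0.187), rod phototransduction genes (0.148), corneal epithelium (0.140), retinal pigment epithelium (0.182) and Bardet-Biedl syndrome genes (0.167) also lay above that range. Lens genes went the other way, with a median SD of 0.074 against 0.107 in random lists, and the crystallin genes Crygc (SD 0.05), Cryab (0.05) and Cryaa (0.09) had mean levels of 13.58, 13.59 and 14.12, near the top of the scale. Ribosomal protein genes had a median SD of 0.056 against 0.101.

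**Figure D1:**
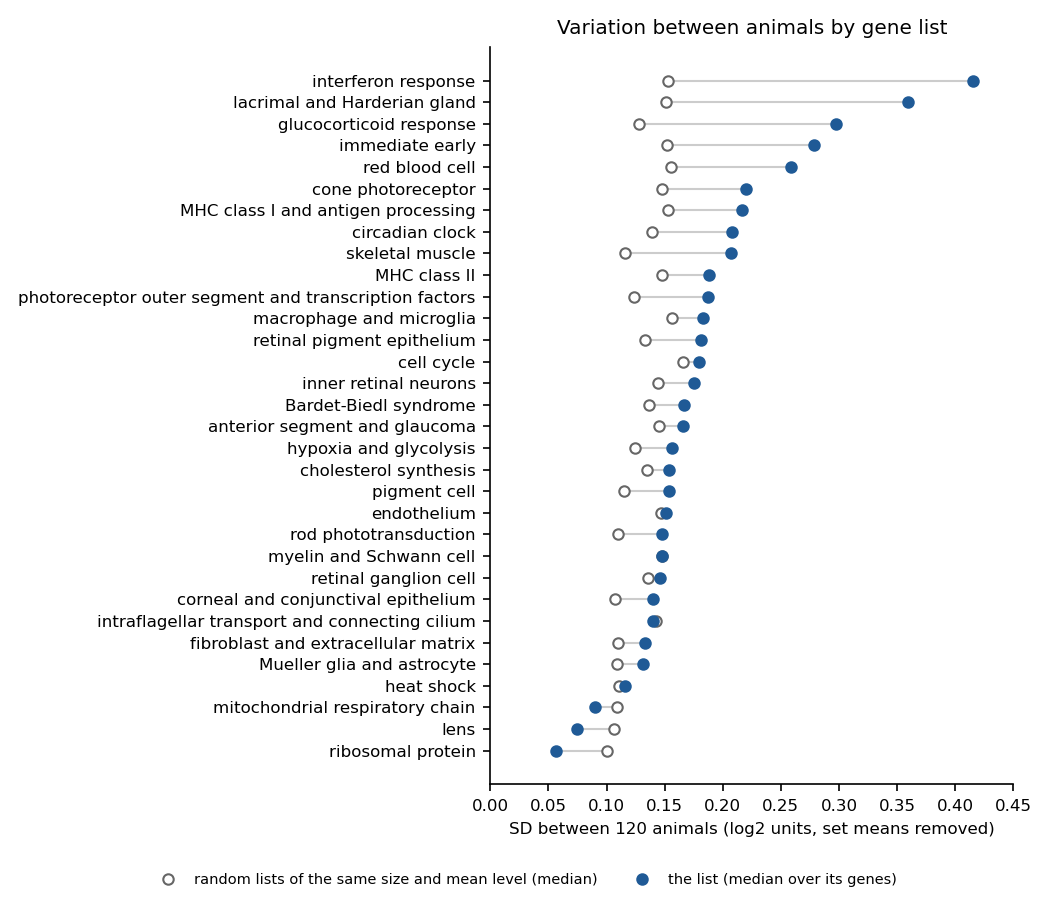
Median SD between the 120 animals (log2 units, processing-set means removed) of each of the 32 gene lists (filled circles) and of random lists of the same size and mean level (open circles, median of 10000 lists). The interferon list has the largest median (0.415), and the ribosomal protein list (0.056) and the lens list (0.074) have the smallest.

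Over all 23326 probe sets tested, 12506 (53.6%) ranged at least 2-fold between the lowest and the highest animal and 1735 at least 4-fold, with a median SD of 0.16. The count of 2-fold ranges rested on the extreme animals: it was 1606 between the 6th lowest and 6th highest animal, 8251 without the 3 rescanned arrays and 7805 without the arrays of animals 63 and 15. With all arrays kept, it was 7901 with L code effects also removed and 2854 with the first 5 principal components also removed. Spiked-in control transcripts, which carry no difference between animals, had a median SD of 0.20 for the 9 hybridisation probe sets and 0.54 for the 12 labelling probe sets, so a typical probe set did not vary more than these controls.

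The S code in the sample titles, which goes with a date where a title holds one and is treated here as a processing set, separated nearly the whole transcriptome. The gene of largest moderated F was Raver1, a splicing co-regulator, with a mean of 5.61 in set 5 and 6.92 in set 7 (12 arrays each, SD between animals within sets 0.16). Adrm1, a proteasome subunit, went from 6.08 in set 2 to 7.57 in set 7, and the retinal GABA receptor gene Gabrr2 from 5.37 in set 5 to 7.16 in set 7, a 3.46-fold difference. The other named genes were Bri3, Mink1, Rbm42, Ring1, Pfkl, Mlf2, Abhd17a, Ubl5 and Ucp2, with differences between 1.73-fold and 2.38-fold. All 12 were highest in set 7, and they were lowest in set 2 (5 genes), set 5 (4 genes) or set 10 (3 genes). Of the genes in the lists, all 14 Bardet-Biedl syndrome genes, all 15 intraflagellar transport genes and 15 of 17 rod genes passed, against 14 of 24 skeletal muscle genes and 6 of 13 interferon genes. By limma's moderated F test over the 10 sets, 21480 of 23326 probe sets (92.1%) passed a Benjamini-Hochberg adjusted p of 0.05, with a median of 25.1% of the variance between sets. The means of the sets were removed before the results on shape and correlation below.

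The L code, a number from 1 to 22 in the titles whose meaning the labels do not give, went with differences in genes of several tissues and processes. Pcdh15, a protocadherin of photoreceptors and hair cells that is mutated in Usher syndrome, had the largest moderated F, with means from 6.50 in L code 19 (6 arrays) to 7.86 in L code 14 (5 arrays) and an SD between animals of 0.40. The rod kinase gene Grk1 ranged from 8.21 to 9.29, a 2.11-fold difference, the cone arrestin gene Arr3 from 7.02 to 7.97, and Ptprn, a phosphatase-like protein of secretory vesicles, from 8.14 to 9.55. Icmt, Lpcat1 (an enzyme of photoreceptor phospholipids), C1h11orf98, Zbtb8a, Syne1, the ciliary gene Cc2d2a, Cdr2 and Cers4 differed between 1.37-fold and 1.69-fold. L code 17 held the highest mean for 6 of these 12 genes.

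Among the lists, the circadian clock had 7 of 17 genes past the L code test over all genes (Bmal1, Per2, Nr1d1, Nr1d2, Dbp, Bhlhe40 and Nfil3) and 12 adjusted over the list alone. The interferon list had 7 of 13 (Irf7, Oas1a, Ifit2, Ifit3, Isg15, Usp18 and Rsad2) and 13 adjusted over the list alone. Rod phototransduction had 6 of 17 (Pde6a, Cnga1, Sag, Grk1, Guca1a and Guca1b) and 8 adjusted over the list alone, MHC class I 4 of 9 and likewise 4 adjusted over the list alone, and the glucocorticoid list 3 of 7 (Fkbp5, Mt2A and Pdk4) and 5 adjusted over the list alone. No skeletal muscle, ribosomal protein, red blood cell or mitochondrial gene passed either way. As list scores, 15 of the 32 lists differed between L codes (permutation p within sets, Benjamini-Hochberg adjusted over 32 lists). The L codes took up 43.4% of the variance of the interferon score (adjusted p = 0.0032). After permuting the codes, the median share over the 32 lists was 19.4% on average. The MHC class I score followed with 42.8% (adjusted p = 0.0032), then fibroblast and matrix with 39.9% (0.0032), pigment cell (adjusted p = 0.0174), outer segment with 38.2% (0.0102), circadian clock with 36.9% (0.0171) and cones with 36.2% (0.0102). Rod phototransduction had 31.5% (0.0363), and the other 7 had 31.2% to 34.7%. L code 13, whose 3 arrays include that of animal 63, held the lowest mean for 21 of the 32 scores.

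**Figure D2:**
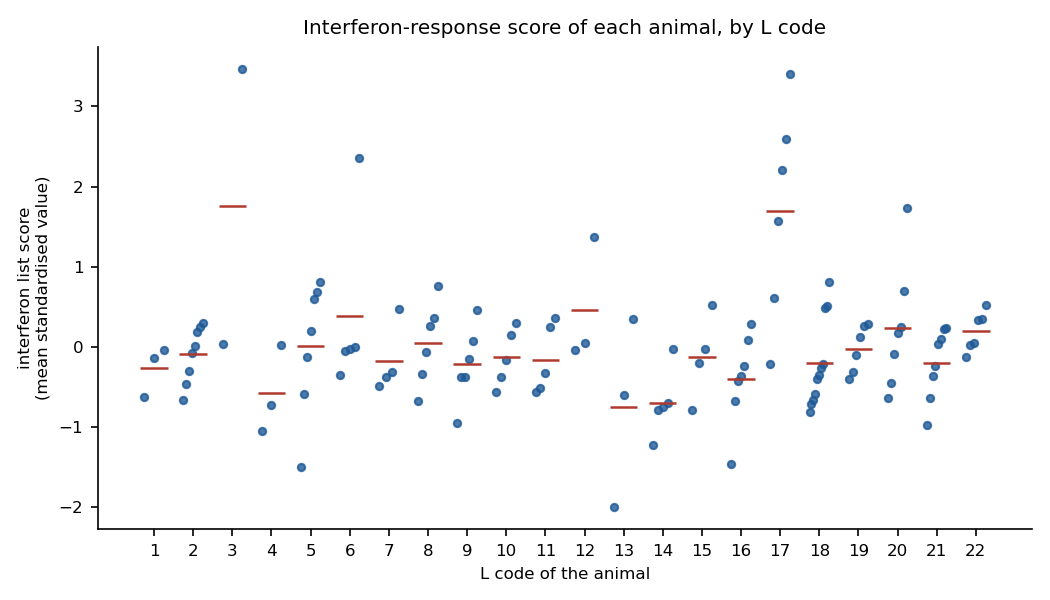
Interferon-response score of each of the 120 animals (points; mean of the 13 genes' standardised log2 values, processing-set means removed), by L code, with the mean of each code (lines). The 6 animals of L code 17 lie between -0.22 and 3.40, and the highest single animal (3.47) is in L code 3.

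With the processing set as a covariate, 1068 of 23326 probe sets (4.58%) passed limma's moderated F test over the 22 L codes, and 4965 had an unadjusted p under 0.05. At the level of genes 659 of 12326 passed (5.35%), and among the list genes 58 of 384. The count was 3003 with no covariate, 474 at an adjusted p of 0.01, and 2123 with the 3' to 5' differences of actin and GAPDH, 2 control transcripts that report RNA integrity and labelling, as covariates.

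At a locus that segregates in an F2, the 3 genotypes stand at 1:2:1, and a gene controlled mainly by such a locus should fall into levels in those proportions. Differences between levels reached 14.8-fold, on 1 of the 3 probe sets of Krt6c. Of 11 such genes measured by several probe sets, 1 had a mixture on more than 1 of them. Krt6c, a keratin gene, had a lower level at 7.55 and its other levels at 11.44 (SD within a level 0.57, n = 120), where another of its probe sets had an SD of 0.17 over the animals. RT1-Bb had 3 levels at 4.91, 7.86 and 8.73 (SD 0.38), and its MHC class II partner RT1-Ba at 4.89, 7.03 and 7.89 (SD 0.34), but a second RT1-Ba probe set with a mixture ran opposite to the first (r = -0.760). Cisd2, an iron-sulphur protein mutated in Wolfram syndrome, stood at 3.97, 6.51 and 7.28 (SD 0.39), the carbonyl reductase gene Cbr1 at 6.70, 8.04 and 8.59 (SD 0.23), and Ccn1 at 4.29, 6.95 and 7.71 (SD 0.45). Smaller steps were found for Fabp12, a fatty acid binding protein (7.45, 8.71 and 9.37), the amylase gene Amy1 (3.38, 4.30 and 5.19), the lysosomal regulator gene Rragd (4.28, 5.09 and 5.61) and Znhit3 (6.85, 7.38 and 7.76). Sv2b and Frmd4b, like Krt6c, had their middle and upper levels at the same value (11.48 and 8.25). Aplf, Ly6c, Ccdc77, Ythdf2, Ramac, Bphl, Pdia5, Mul1, Pla2g2a and Krtap14l had 3 ordered levels, while Cdh22 and the X-linked genes Huwe1 and Gla did not. Of these named genes Krt6c, Sv2b, Frmd4b, Ccn1, Ythdf2 and Pla2g2a had a lower BIC with 2 levels at 1:3 than with 3 at 1:2:1. The 25 named genes shared 10 with the 25 of largest SD.

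**Figure D3:**
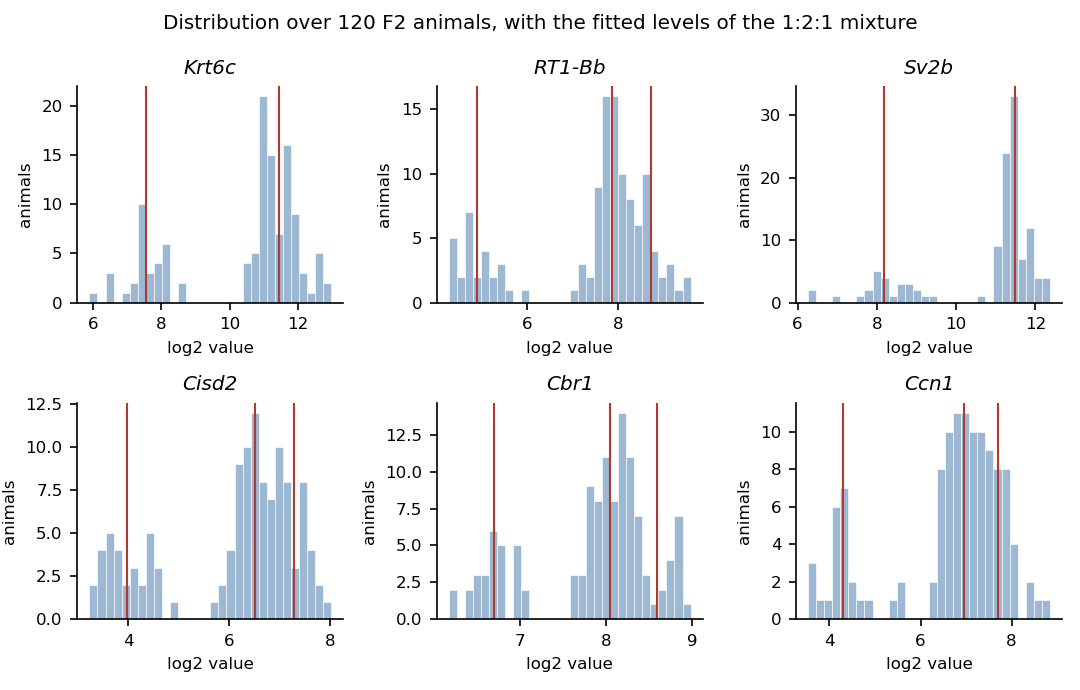
Histograms of the log2 values of 6 genes over the 120 animals (x axis, log2 value with processing-set means removed; y axis, number of animals), with red lines at the fitted levels of the 1:2:1 mixture. The lower level of RT1-Bb is at 4.91 and its others are at 7.86 and 8.73, and Krt6c and Sv2b show 2 separate levels.

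In all, 59 of 23326 probe sets had a Bayesian information criterion (BIC) lower by more than 10 for the 1:2:1 mixture than for the best of 3 single distributions, where 2 were called on values simulated from single distributions. They comprised 26 probe sets with 1 symbol, for 25 genes, and 33 with several symbols or none. The median span between the outer levels was 2.17 log2 units (4.51-fold), and 51 had 3 separate levels in order. Of the 59, 39 had their lowest BIC with 3 levels at 1:2:1, 16 with 2 levels at 1:3, 3 with 2 levels at 1:1 and 1 with 2 levels at 3:1. In males an X-linked gene has 2 genotypes at 1:1, and of the X-linked pair Gla was among those at 1:1 and Huwe1 was the one at 3:1. The share called was 0.253%, against 0.497% without removal of set means, 0.141% at a BIC difference over 20 and 0.0772% with L code effects also removed. In values redrawn from the 59 fitted mixtures, 53.2 on average were called again with nothing removed. The mean was 33 after removal of set means and 4.55 after removal of set and L code effects. The redrawn values held no set or L code effect, so both removals lose mixtures of this size even where there is none. Whether the calls that changed in the data were lost mixtures or shapes made by code effects cannot be told from them.

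Genes next to each other on a chromosome varied together more than genes apart. The largest correlation between neighbours was between Naa35, a subunit of an N-terminal acetyltransferase, and Agtpbp1, a carboxypeptidase that removes glutamate from tubulin, on chromosome 17 (r = 0.911, rho = 0.885). On chromosome 11 came the keratin-associated gene Krtap14l with LOC100363236 (r = 0.884, rho = 0.895), the adhesion gene Alcam with the ubiquitin ligase gene Cblb (r = 0.863, rho = 0.794) and the partners Parp9 and Dtx3l (r = 0.841, rho = 0.727). Ap1s3 and Wdfy1 (r = 0.831, rho = 0.691), Serpinb6a and the quinone reductase gene Nqo2 (r = 0.828, rho = 0.846), Top2b and Ngly1 (r = 0.825, rho = 0.732), Steep1 and Ube2a (r = 0.820, rho = 0.714), RGD1309362 and Ifgga2l1 (r = 0.806, rho = 0.689) and the stress factor gene Ddit3 with the tRNA synthetase gene Mars1 (r = 0.806, rho = 0.842) followed. Both coefficients of all 10 pairs had a permutation p of 1e-05 (two-sided), the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over these 10, which were picked as the largest of 11862. Without the 2 animals farthest from the median of the first gene, r lay between 0.710 and 0.899, and within the 10 processing sets between 0.028 and 0.982, positive in every set. With the first 5 principal components removed as well, the pair Steep1 and Ube2a fell to 0.0197, Ap1s3 and Wdfy1 to 0.314, Top2b and Ngly1 to 0.403 and Alcam and Cblb to 0.543. Parp9 and Dtx3l, Serpinb6a and Nqo2, and Ddit3 and Mars1 overlap each other in the assembly, so these pairs are not separate stretches of the chromosome.

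Pairs whose symbols share a name stem (the same first letters) were left out here and at the distances below. Over the remaining 11862 pairs of neighbours, the mean absolute r was 0.25 against 0.222 after shuffling gene positions. The difference was 0.0284 (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). Without the 793 pairs of overlapping genes it was 0.0283 (p = 0.001 by the same test). The mean fell with distance, to 0.243 for genes 2 apart, 0.236 for 10 apart and 0.227 for 100 apart. Gene order came from the GRCr8 assembly. Among the 25 mixture genes, the 21 pairs on 1 chromosome, the pair of one name stem left out, had a mean absolute r of 0.398 against 0.074 in 278 pairs on different chromosomes, a difference of 0.324 (permutation p = 0.0001, one-sided, the smallest of 10000 permutations).

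**Figure D4:**
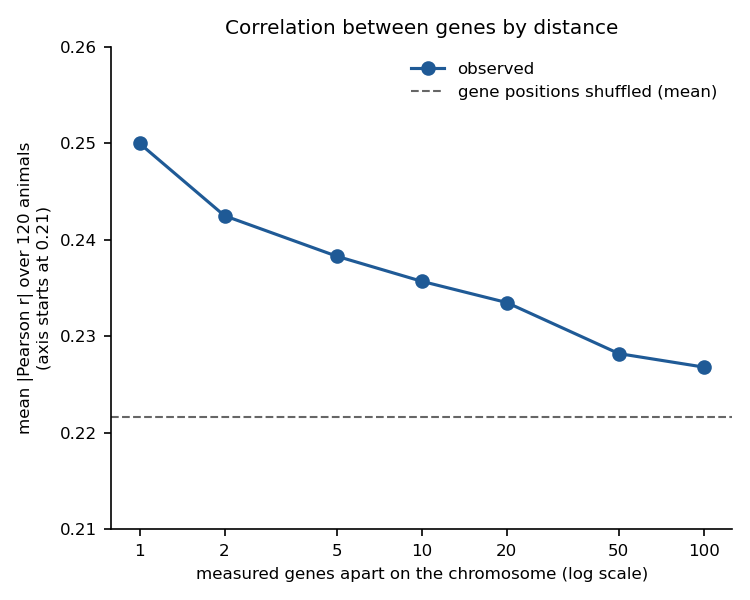
Mean absolute Pearson r over the 120 animals between genes on 1 chromosome (y axis, starting at 0.21) against how many measured genes they are apart (x axis, log scale), with a dashed line at the mean after shuffling gene positions. Pairs of one name stem are left out. The points fall from 0.25 for neighbours to 0.227 at 100 genes apart, and the line is at 0.222.

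Genes of the same tissue or process varied together in 17 of the 32 lists. The interferon list had the largest mean correlation between its genes (0.638), with all 78 pairs positive and r = 0.936 for Mx1 and Isg15 (rho = 0.883). Pigment cell genes followed (0.603), with the melanin enzymes Tyr and Dct at r = 0.743 (rho = 0.688). Skeletal muscle genes had a mean of 0.602, with troponin Tnnc2 and enolase Eno3 at r = 0.928 (rho = 0.913). Glucocorticoid-response genes (0.529) were led by Tsc22d3 and Pdk4 (r = 0.855, rho = 0.841). The Bardet-Biedl syndrome genes, whose products carry cargo to cilia, had a mean of 0.467, with Bbs5 and Lztfl1 at r = 0.824 (rho = 0.721), and the intraflagellar transport genes a mean of 0.306, with Ift81 and Ift88 at r = 0.667 (rho = 0.440). Both list scores also followed the actin 3' to 5' difference (r = 0.515, rho = 0.516 and r = 0.541, rho = 0.530, permutation p = 1e-05, adjusted p = 0.00016 over 32 lists, both p values of r).

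The remaining lists with correlated genes were cholesterol synthesis (mean r 0.394, Dhcr7 and Msmo1 at 0.768), ribosomal protein (0.382, Rpl5 and Rps24 at 0.816), red blood cell (0.354, Hbb and Alas2 at 0.928), lens (0.336, Cryba2 and Crygs at 0.874), corneal and conjunctival epithelium (0.331, keratins Krt13 and Krt4 at 0.815), rod phototransduction (0.329, Gnat1 and Rcvrn at 0.842), MHC class I (0.312, RT1-S3 and B2m at 0.829), fibroblast and matrix (0.309, Col6a1 and Col6a2 at 0.741), macrophage and microglia (0.190, C1qa and C1qc at 0.80), immediate early (0.187, Fos and Egr1 at 0.765) and cell cycle (0.172, Ccna2 and Pcna at 0.686). In the red blood cell list the next pair after Hbb and Alas2 was Slc4a1 and Ahsp, with r = 0.349 (rho = 0.212). Circadian clock genes did not vary as 1 group (mean r 0.070, adjusted p = 0.920). Nor did the genes of heat shock (0.307), retinal ganglion cell (0.287), MHC class II (0.227), mitochondrial (0.205), lacrimal and Harderian gland (0.205), Mueller glia (0.180), outer segment (0.167), cone (0.132), endothelium (0.115), inner retinal neuron (0.106), hypoxia (0.0987), pigment epithelium (0.0816), myelin (0.0399) and glaucoma (-0.0696) pass. Lists were compared with 10000 random lists of matched mean level (one-sided permutation p, Benjamini-Hochberg adjusted over 32 lists), and the adjusted p of the interferon list was 0.00107. With 5 principal components removed 26 lists passed, while the mean r of the Bardet-Biedl syndrome list fell to 0.108 and that of the intraflagellar transport list to 0.0805. The 9 additional lists were heat shock, retinal ganglion cell, MHC class II, mitochondrial, gland, outer segment, cone, endothelium and inner retinal neuron. With each gene read from its probe set of largest SD, the intraflagellar transport (mean r 0.114, adjusted p = 0.131), ribosomal protein (0.217, adjusted p = 0.064) and fibroblast and matrix lists (0.192, adjusted p = 0.0952) no longer passed, and the glucocorticoid list fell to 0.309 but passed. The fibroblast and matrix list also failed with L code effects removed (0.257, adjusted p = 0.101). Without animal 63, 21 passed, the additional ones being retinal ganglion cell (0.265), MHC class II (0.243), lacrimal and Harderian gland (0.213) and outer segment (0.147), while the ribosomal protein list fell to 0.233 (adjusted p = 0.0076). Among lists that did not pass, heat shock fell to 0.199, mitochondrial to 0.106, Mueller glia to 0.104, circadian clock to 0.0366 and hypoxia to 0.0349 without that animal. Leaving out animal 77 lowered the gland list to 0.137, cones to 0.0686 and inner retinal neurons to 0.0624. Retinal ganglion cell and MHC class II genes also passed by rho (0.241 and 0.236), as did mitochondrial genes (0.170), and with the actin and GAPDH differences regressed out (0.307 and 0.240), as did the heat shock (0.344) and gland lists (0.219). The named pairs, up to 3 per list and 51 in all, were the largest of each list. Their permutation p for r was 1e-05, the smallest possible, in 49 and 0.0032 at most after adjustment over the 51, and 0.0265 at most for rho. Over these pairs rho lay between 0.212 and 0.926, r without the 2 farthest animals between 0.178 and 0.919, and 47 of the 51 were positive within each processing set, in which r ranged from -0.362 to 0.994.

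The 6 list pairs with the most positive correlations between their scores were picked as the largest of 496. The scores of the Bardet-Biedl syndrome and intraflagellar transport lists had the largest correlation (r = 0.893, rho = 0.818), followed by MHC class I with interferon response (r = 0.865, rho = 0.741) and rod phototransduction with the outer segment list (r = 0.860, rho = 0.805). Inner retinal neurons went with retinal ganglion cells (r = 0.732, rho = 0.603) and with cones (r = 0.723, rho = 0.532), and hypoxia and glycolysis genes with the mitochondrial chain (r = 0.715, rho = 0.490). For these 6, both permutation p were 1e-05, the smallest possible, and r was positive in all 10 processing sets, between 0.100 and 0.976. Without the 2 farthest animals it lay between 0.498 and 0.838. Dropping animal 63 left r = 0.524 for hypoxia and glycolysis with the mitochondrial chain. Dropping animal 77 left 0.642 for inner retinal neurons with ganglion cells and 0.60 with cones. For the other pairs, r without the animal that moved it most was between 0.836 and 0.851.

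Of the 6 most negative correlations, 5 set scores of the retina or its pigment epithelium against those of other tissues. Lacrimal and Harderian gland genes ran against inner retinal neurons (r = -0.427, rho = -0.257, adjusted p = 0.0141), cones (r = -0.407, rho = -0.189, adjusted p = 0.028) and the retinal pigment epithelium (r = -0.357, rho = -0.303, adjusted p = 0.00241). The first 2 of these rested on animal 77, which had the highest gland score (3.38) and the lowest scores of inner retinal neurons (-2.50) and cones (-2.99). With set means and scores made anew without its array, r was -0.168 for inner retinal neurons (adjusted p = 0.158), -0.105 for cones (0.397) and -0.263 for the pigment epithelium (0.0221). Dropping the animal from the scores already made gave -0.208, -0.159 and -0.284. Rod genes ran against fibroblast and matrix genes (r = -0.379, rho = -0.468, adjusted p = 0.000893) and against macrophage genes (r = -0.371, rho = -0.369, adjusted p = 0.000893), the latter in all 10 sets. These scores also went in opposite directions with the GAPDH 3' to 5' difference, at r = -0.365 for rods (rho = -0.346, adjusted p = 0.0041), 0.299 for fibroblasts (rho = 0.348, adjusted p = 0.0153) and 0.234 for macrophages (rho = 0.292, adjusted p = 0.0489, over 32 lists). For the actin difference r was -0.338 (rho = -0.306, adjusted p = 0.00424), 0.271 (rho = 0.310, adjusted p = 0.0227) and 0.206 (rho = 0.246, adjusted p = 0.0876). With both differences regressed out, rods against fibroblast genes had r = -0.308 (adjusted p = 0.00614) and rods against macrophage genes -0.311 (0.00613). Red blood cell genes ran against ribosomal protein genes (r = -0.343, adjusted p = 0.00799), but rho was -0.143 (adjusted p = 0.259) and 6 of the 10 sets had that sign, and without animal 63 r was -0.209 (adjusted p = 0.101). The adjusted p of rho for glands against cones was 0.130. Without the 2 farthest animals, r of these 6 pairs lay between -0.378 and -0.191, and within sets between -0.903 and 0.419.

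Of 496 list pairs, 190 passed a permutation test of r within sets (two-sided, Benjamini-Hochberg adjusted over 496 pairs), 171 positive and 19 negative. The share of 38.3% depended on animal 63. It was 24.4% without that array, 24.6% without those of animals 63 and 15, and 23.8% without the 3 rescanned arrays, which include it. Over all arrays it was 23.6% by rho and 19.8% after removal of 5 principal components. The split of 171 to 19 became 83 to 35 without the rescanned arrays, 87 to 35 without those of animals 63 and 15, and 85 to 36 without animal 63 alone.

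**Figure D5:**
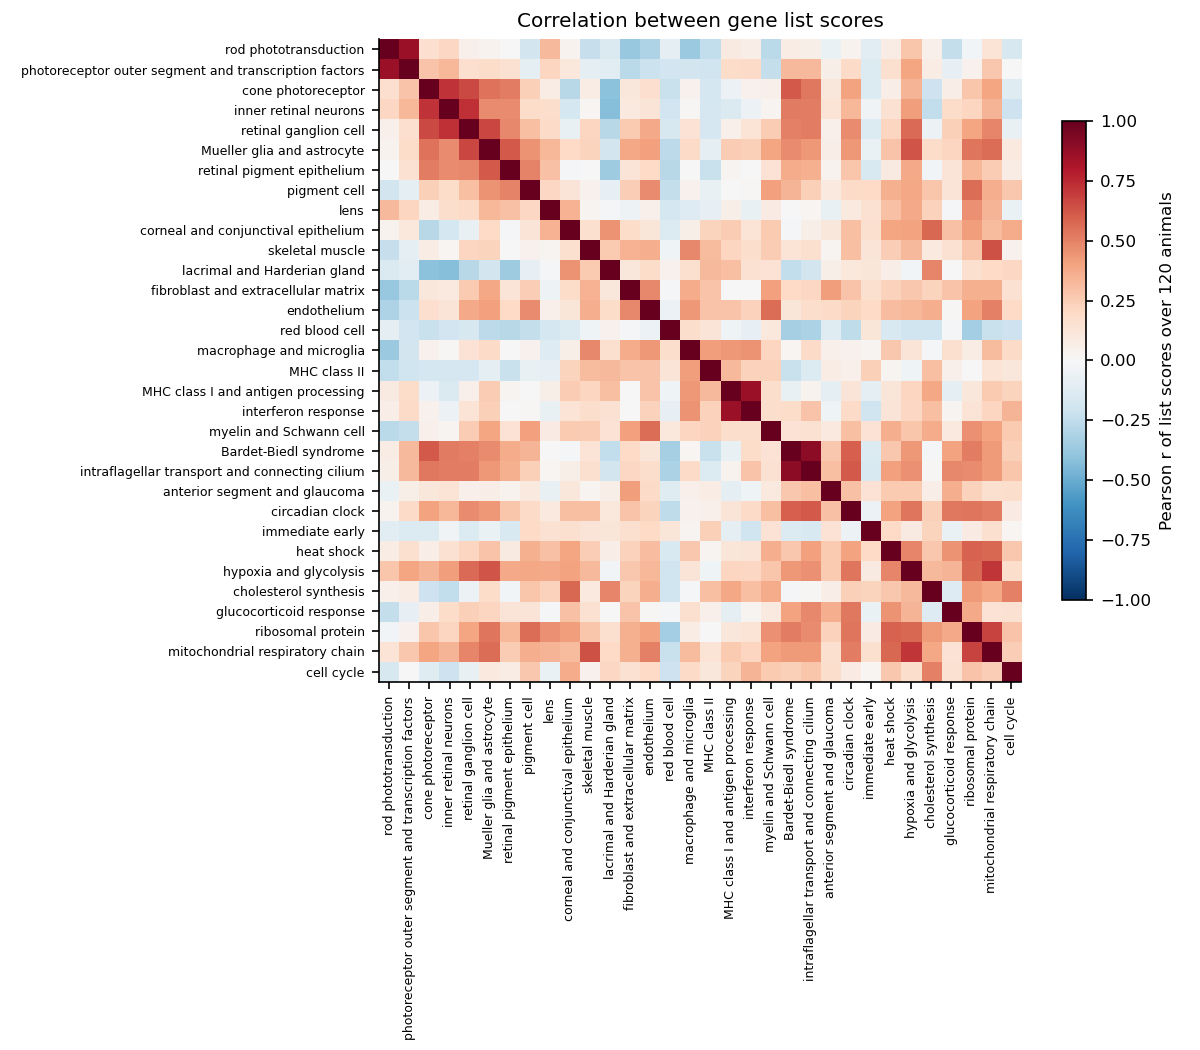
Pearson r over the 120 animals between the scores of all 32 gene lists (colour, from -1 in blue to 1 in red; the diagonal is 1 by definition). The darkest pairs off the diagonal are the Bardet-Biedl syndrome and intraflagellar transport lists (0.893), the MHC class I and interferon lists (0.865) and the rod and outer segment lists (0.860).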

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

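Leaving out the 2 arrays least like the rest, or animal 63 or 77 alone, the actin and GAPDH settings, the interferon covariate, the removal of overlapping pairs and, for variation between animals, the removal of 5 principal components were chosen only after results were seen, as was the limit of 1.5-fold for calling an SD the same (before, any change smaller than the SD itself). Signs were compared only for the neighbour difference, the named neighbouring pairs and the named list pairs, and none reversed under any setting run. Counts, SDs, code tests and mixtures were compared only by size or threshold, so a reversal could not be seen there. The sign of r between RT1-Bb and RT1-Ba depended on the RT1-Ba probe set. The count of 2-fold ranges went from 12506 to 1606 between the 6th lowest and 6th highest animal, 8251 without the rescanned arrays, 7901 with L code effects removed, 7805 without the 2 arrays and 2854 with 5 principal components removed. The count between the 6th lowest and 6th highest animal leaves out the extreme values by definition. Both groups of arrays left out include that of animal 63, which held 49% of the second principal component, itself 14.1% of the variance. How much of those falls was due to this array was not tested. For the removals of L code effects and of components the cause was not tested either. For L codes the count of 1068 became 474 at the stricter threshold, 3003 with no covariate (835 shared) and 2123 with actin and GAPDH as covariates (1064 shared), where the cause was not tested. The share of mixtures went from 0.253% of probe sets to 0.141% at a BIC difference over 20, 0.497% without removal of set means (53 of 59 shared) and 0.0772% with L code effects removed (17 shared). Redrawn mixtures held no set or L code effect. They were called more often with nothing removed (53.2 of 59) than after removal of set means (33) or of both effects (4.55). Each removal thus loses calls even without such an effect. Whether the calls that changed in the data were lost mixtures or shapes made by code effects cannot be told from the redraw. With 5 principal components removed, 26 lists in place of 17 were correlated within and 19.8% of list pairs in place of 38.3%. The latter share was 23.6% by Spearman rho, 23.8% without the rescanned arrays, 24.6% without the 2 arrays and 24.4% without animal 63 alone. Animal 63, part of both groups of arrays left out, thus accounted for nearly all of these last changes, and for the other list values the cause was not tested.

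Other settings gave 10072 to 16305 probe sets for variation, 19964 to 27157 for S codes, 977 to 1352 for L codes, 0.193% to 0.334% with a mixture, a neighbour difference of 0.0224 to 0.0327, 14 to 21 lists and 36.7% to 46.2% of list pairs. Of the named results, all 180 S code and 84 L code values stayed past the threshold, as did 79 of 80 for neighbouring pairs, all but 13 for list pairs and 163 of 200 for mixture genes. SDs of the 25 most variable genes stayed within 1.5-fold in 193 of 200, and the other 7 were all with 5 principal components removed. Of 352 values of single lists, 29 newly passed and 4 no longer did (ribosomal protein, intraflagellar transport, and fibroblast and matrix by another probe set per gene, and the last also with L code effects removed). No paired analysis was possible because the labels give only 1 group.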

Other observations

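The pairs of mixture genes described here, L code 17, and the tests of the Bardet-Biedl syndrome list by actin and GAPDH and by leaving out 2 arrays, and of the mixtures by chromosome and by middle level, were chosen only after results were seen. Mixture genes on 1 chromosome often ran together or in opposite directions. Mul1, a mitochondrial ubiquitin ligase gene, and the phospholipase gene Pla2g2a, both on chromosome 5, had r = -0.859 (rho = -0.886), Cbr1 and Krtap14l on chromosome 11 had r = 0.830 (rho = 0.818), and RT1-Bb and RT1-Ba on chromosome 20 had r = -0.744 (rho = -0.840). Each p was 1e-05 by permutation, the smallest possible, and 2.2e-05 for r and 2e-05 for rho after adjustment over 22 pairs, of which 15 passed for r. Without the 2 farthest animals r was -0.862, 0.825 and -0.736, and within processing sets it ranged from -0.923 to -0.799, from 0.667 to 0.979 and from -0.830 to -0.652. The sign for RT1-Ba depended on the probe set, since its other probe set with a mixture had r = 0.944 with RT1-Bb (rho = 0.909, adjusted p = 2e-05 for both over 4 probe sets, 0.939 without the 2 farthest animals, 0.864 to 0.979 within sets). The X-linked pair Huwe1 and Gla had r = -0.0357 (rho = -0.122, adjusted p = 0.701 and 0.227), -0.0515 without the 2 farthest animals and -0.509 to 0.357 within sets.

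Interferon scores were high in few animals. Animal 13 of L code 3 had the highest score (3.47), and 4 of the 10 highest were in L code 17, whose 6 animals came from processing sets 5 to 9. The mean of all animals outside that code was -0.09, and the skewness over all animals was 1.70.

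The S codes differed in 21480 probe sets, where the highest of 99 other assignments gave 35. For the L codes the count was 1068 against 562. In each case 1 of 100 assignments, the real one, gave as many, the least that 99 draws can show. This argues against chance as the reason but cannot exclude it.

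For the L codes, RNA integrity or labelling as read by actin and GAPDH is argued against as the whole cause, since 2123 probe sets passed with these covariates, and so is the interferon response of a few animals, since 1145 passed with that score as covariate. A candidate explanation that stays open is the time of day at which eyes were taken. Over the 22 L codes the mean score of Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp and Tef ran opposite to that of Bmal1, Npas2, Clock and Nfil3 (r = -0.3727, rho = -0.432, one-sided permutation p of r = 0.0433, r = -0.407 without the 2 farthest codes). These groups also ran opposite over animals within L codes (r = -0.250), so the relation is not particular to the codes, and the other effects of an L code, shared parents among them, were not tested.

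The mean r of the Bardet-Biedl syndrome list, 0.467, stayed at 0.4099 with the actin and GAPDH differences regressed out and at 0.3943 without the 2 arrays least like the rest, which argues against either as the whole cause. Against lists matched on mean level and on correlation with the first principal component, whose median was 0.313, its p was 0.0003, while that of the intraflagellar transport list was 0.07. With 5 principal components removed the mean r was 0.108, so most of it lay in components shared by many genes, and what those components stand for may be technical and was not determined. No biological explanation was tested.

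For the mixtures, batches or odd arrays in place of segregating loci are argued against, since genes on 1 chromosome had a mean absolute r higher by 0.3238 than those on different chromosomes. In the 51 with 3 ordered levels the middle level lay at a median of 0.4951 of the way between the outer levels on the linear scale (95% bootstrap interval 0.476 to 0.519) and at 0.683 on the log2 scale. Such a position would be seen if each allele added its own amount of signal. The bootstrap treated probe sets as independent, although some genes on 1 chromosome were correlated, so the interval may be too narrow. Over all 59 the linear median was 0.502 (0.479 to 0.523), but for Krt6c, Sv2b and Frmd4b the middle and upper levels were the same. Further, 16 of the 59 had their lowest BIC with 2 levels at 1:3, and of these Ccn1, Ythdf2 and Pla2g2a were among the 51. A probe sequence that binds the transcript of one strain poorly would give the same spacing and linkage, and could not be told apart from a difference in level: the median over 11 genes of the highest r with another probe set of the gene was 0.1154, just above the middle 95% of medians from unrelated probe sets and below the 0.264 of other genes. That r was 0.932 for Ccdc77, 0.852 for Cisd2, 0.823 for Huwe1 and 0.504 for Krt6c, but the SD of those other probe sets was smaller, at 0.47 against 0.62, 0.27 against 1.33, 0.28 against 0.79 and 0.17 against 1.82, and in the other 7 genes r was 0.396 at most (Frmd4b), with RT1-Ba at 0.0521 (lowest -0.760) and Ramac at -0.316.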
